A study of Gallus gallus with 403 samples.

How the data were processed

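The labels of all 403 arrays describe total RNA extracted with Trizol, biotin-labelled cRNA made by the Affymetrix protocol and hybridisation to the Affymetrix Chicken Genome array. Values were deposited as log2 intensity, 1 per probe set and array, and were used on that scale. Per the submitters' processing notes, the authors made them with Affymetrix Expression Console 1.1; the normalization is not given in the sources used here. The table held 38535 probe sets, of which 96 controls were left out. Signal served in place of depth: array medians lay between 6.05 and 6.47 in the first run of sample numbers and between 5.99 and 6.18 in the second, with values from 3.21 to 15.79 and from 3.01 to 15.26.

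Tissue, age and replicate number were taken from the sample titles and source names, and sex from a separate label, since the titles do not give it. In the second run of sample numbers the free descriptions named other tissues or ages than the titles, and the titles were used. For 6 pectoralis arrays the title and the source name gave different ages, and these entered no comparison of ages. Of the 38439 other probe sets, 27168 carried 1 gene symbol, 177 several and 11094 none; only the first kind was tested, and 26853 of them were matched to the gene table by gene number. In each fit a gene was represented by its probe set with the highest mean over the arrays of the fit. Before that choice, probe sets whose highest group mean lay under the 25th percentile of all values of the fit were left out.

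Comparisons, models, thresholds, gene lists and the rule for naming genes were fixed before the values were seen. Linear models with 1 mean per group and moderated statistics (limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package) gave log2 differences, and p-values were adjusted by Benjamini and Hochberg over the genes of a contrast. For organ classes at day 7, each class (the mean of its tissues with equal weight) was set against the mean of the other 9 classes, and a gene was counted at an adjusted p under 0.05 and a log2 difference of at least 2. For the 18 comparisons of 2 groups the absolute log2 difference had to be at least 1. Ages were compared within 1 tissue and 1 run of sample numbers, in a fit of all its ages. Labelled sex was compared with tissue and age as a block of fixed effects, at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

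Genes named in the report passed these thresholds and were taken in order of the absolute log2 difference, up to 8 per organ class and 12 per direction in other comparisons, when the arrays of the 2 groups did not overlap. Up to 4 members per gene list were named by size of difference, and members that had not passed were named as such. In comparisons without calls, named genes are members of the gene lists. The 40 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated one, adjusted over the lists of a contrast; lists with under 5 measured members were not tested. Of 380 tests in organ classes 202 passed and 144 of these passed with an estimated correlation, of 684 in comparisons of 2 groups 164 and 41, and of 39 for sex 2 and 0.

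The procedure was tested on simulated data with 50 changed genes per size. At a log2 difference of 2 it recovered 100% in a design like liver, 96% for lung, 94% for ileum, 90% for testes and 86% for the growth plate. For a log2 difference of 3 in an organ class it recovered 100%, and for 0.2 between sexes 90%.

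Replicate numbers were checked for pairing, by the correlation of deviations from the group means between arrays of the same number. Arrays of the same number went together throughout in lung at days 28 and 7 (correlations from 0.316 to 0.654), ileum and jejunum (0.19 to 0.626) and testes and ovary (0.104 to 0.484). In these, 2 of 4, 4 of 4 and 3 of 3 arrays went best with their own number. The labels name no pairs, so this need not be a paired design. With the number as a block these gave 0, 0 and 3860 calls, against 0, 0 and 3835.

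Alternatives were no filter on dim probe sets or one at the 50th percentile, quantile normalization, centring each array on its median, the mean of all probe sets of a gene, array weights, moderation with trend and robust fitting, labelled sex as a covariate, replicate number as a block, only the 2 groups compared, each replicate number left out in turn, other ages or sets of arrays, and a fold threshold against every other organ class. Other splits of the arrays, all of them or 100 drawn, were fitted to see how many genes chance calls.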

Results

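RNA from tissues of the chicken, Gallus gallus, was hybridised to Affymetrix Chicken Genome arrays, and 403 arrays were analysed in 101 groups of 1 tissue and 1 age. Of these groups, 94 held 4 arrays, 5 held 3 and 2 held 6. The tissues were abdominal fat, brain, cerebral cortex, pineal gland, retina, duodenum, jejunum, ileum, whole intestine, cecal epithelia, liver, lung, spleen, pectoralis (breast) and gastrocnemius (leg) muscle, the growth plate of the tibiotarsus (a leg bone), ovary, ovarian cortex, oocytes and testes. Most were labelled with an age between day 0 and day 56, and gonads with weeks 16 to 21 or year 2. The labels do not say from which event days were counted. The arrays carry 2 runs of sample numbers, used here as batches. A run need not be 1 batch, since within the first the lowest value of an array also differed between groups. It lay between 3.29 and 3.32 in retina at day 35, for example, and between 3.64 and 3.68 at day 9. The first held 251 arrays of 63 groups with array medians between 6.05 and 6.47 on the log2 scale, and the second 152 arrays of 38 groups with medians between 5.99 and 6.18. Labels number the replicates but do not say that these were separate birds. The p-values thus measure only the spread between arrays, pooled over the groups of a fit, and it may be technical. That spread came in 2 sizes, and where a fit held both, the pooled SE was too small for groups of the wider spread. The median over probe sets of the SD between the arrays of a group lay between 0.0896 and 0.202 in 45 groups, and between 0.372 and 0.537 in the other 18 groups of the first run and all 38 of the second.

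**Figure D1:**
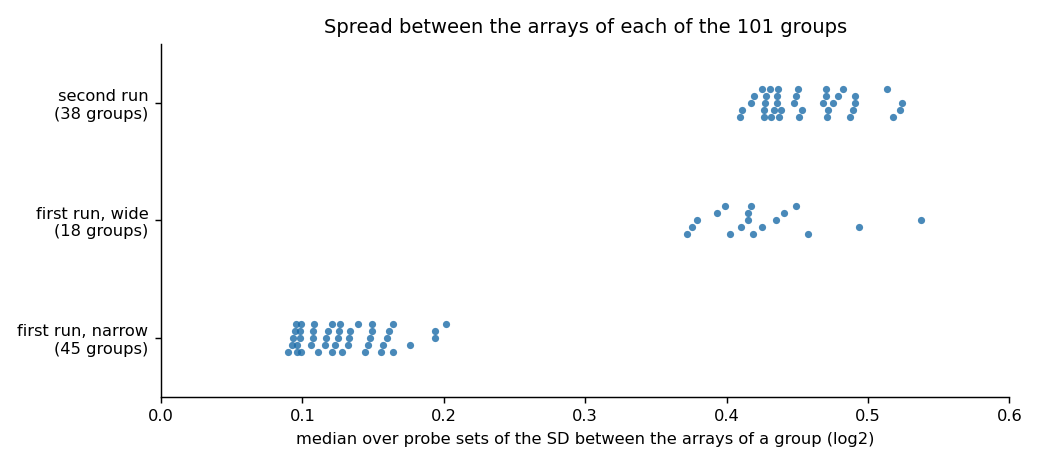
Median over probe sets of the SD between the arrays of a group (log2, x axis), 1 point per group, for the 2 runs of sample numbers; points are shifted up or down only to be seen. The 45 groups of narrow spread lie at or below 0.202, and the 56 others at or above 0.372.

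Which genes set each organ apart was compared at day 7, the age with the most organs, between 10 organ classes on 52 arrays (12985 genes). A gene was counted when it lay at least 4-fold above the mean of the other 9 classes. Differences below are log2 ± SE of 4 arrays against 48, except intestine (12 against 40) and muscle (8 against 44), and every count of list members given for an organ was the same when adjusted over the list alone. At day 7 fat, spleen, retina and growth plate came only from the second run, and liver, lung, pineal gland, muscle and the brain arrays used here from the first. With groups of the first run only, taking the ages nearest day 7, the 10 counts lay between 306 and 545, each within 1.5 times the count at day 7, and all 45 genes and 29 lists tested again kept their direction and their side of the thresholds. The calls tested again thus did not need a difference between runs. Liver, lung, pineal gland, muscle and brain kept the same arrays there, so this does not tell how other arrays of these organs would come out. Brain of the same label differed between the runs in 3656 genes, and its second set gave fewer calls, as given below.

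In liver, 519 genes lay above the other organs, led by secreted plasma proteins. FGG and FGB, which encode chains of fibrinogen, lay 8.10 ± 0.24 and 7.50 ± 0.26 above, ALB, serum albumin, 8.05 ± 0.34, and the antimicrobial beta-defensin AvBD9 8.13 ± 0.22. Of 33 measured genes of hepatocyte secretion 30 passed (adjusted p = 4.31e-73). So did 15 of 24 of xenobiotic and bile acid metabolism (2.41e-17), among them CYP7A1, the rate-limiting enzyme of bile acid synthesis (4.48 ± 0.24). Passing too were 9 of 17 of gluconeogenesis and glycogen (2.12e-11), among them TAT, tyrosine aminotransferase (6.95 ± 0.23). Intestine held 362 such genes, with RBP2, a retinol carrier of enterocytes, at 7.85 ± 0.13, the fatty acid binding protein FABP1 at 7.45 ± 0.14 and the peptide transporter SLC15A1 at 6.86 ± 0.20. There 23 of 28 genes of enterocytes and digestion (3.62e-47) and 19 of 24 of nutrient transport (4.47e-31) passed, the sucrase gene SI at 6.64 ± 0.16 among the former. Genes of the exocrine pancreas passed in intestine too (2 of 14, adjusted p = 1.95e-05), with the amylase gene AMY2A at 2.06 ± 0.15; the median level of that list relative to all groups was 2.75 in duodenum, 0.18 in jejunum and 0.35 in whole intestine.

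In muscle, 336 genes lay above, nearly all of the leading ones parts of the sarcomere: the fast troponins TNNC2 and TNNI2 at 8.38 ± 0.17 and 8.14 ± 0.18, the myosin light chain MYL1 at 7.97 ± 0.17 and titin, TTN, at 7.74 ± 0.15. Of 28 contractile genes 26 passed (adjusted p = 3.91e-65), of 14 fast-fibre genes 13 (3.38e-41) and of 18 slow-fibre genes 12 (1.4e-21). The median level of the slow-fibre list relative to all groups was 5.04 in gastrocnemius and 0.74 in pectoralis. The growth plate held 318, with LECT1, a cartilage matrix protein, at 8.63 ± 0.24, COL10A1, the collagen of hypertrophic cartilage, at 8.02 ± 0.25 and COL2A1, the main cartilage collagen, at 7.25 ± 0.28. Cartilage genes passed in 22 of 27 cases (1.6e-51) and bone genes in 9 of 17 (2.49e-11), with the mineral-binding IBSP at 6.08 ± 0.24. Stress and immediate early genes were also higher in the growth plate (10 of 22, adjusted p = 1.73e-11), with CYR61 at 4.82 ± 0.27 and ATF3 at 3.82 ± 0.31.

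In brain, 595 genes lay above, with the neurofilament NEFM at 5.69 ± 0.27, the glutamate receptor subunit GRIN1 at 5.50 ± 0.22 and ZIC1, a transcription factor of the cerebellum, at 5.89 ± 0.23. Neuronal genes passed in 20 of 23 cases (adjusted p = 3.42e-34), myelin genes in 11 of 17 (1.9e-14; MBP, a myelin sheath protein, 4.76 ± 0.28) and astrocyte genes in 8 of 14 (1.62e-09; GFAP 4.74 ± 0.24). The direction of both genes was reversed with the second set of brain arrays of the same label (MBP −2.33, GFAP −0.5) and at day 21 (−2.24 and −0.5). Neither list passed there: the median of the myelin list, 2.7 here, was −0.34 in the second set (adjusted p = 0.272) and −0.25 at day 21 (0.107), and that of the astrocyte list, 2.35 here, 0.09 (0.0654) and 0.29 (0.226). Retina held 461, with PDE6H, the cone phosphodiesterase, at 7.65 ± 0.21 and the red cone opsin OPN1LW at 6.87 ± 0.23. There 20 of 26 photoreceptor genes (4.54e-34) and 15 of 23 neuronal genes (2.57e-21) passed. The pineal gland held 375, with TPH1, the first enzyme on the way from tryptophan to melatonin, at 8.79 ± 0.21 and ASMT, its last enzyme, at 6.98 ± 0.23. Of 16 genes of melatonin synthesis 10 passed (3.23e-21). Of the photoreceptor genes 7 of 26 passed in the pineal gland as well (adjusted p = 0.0179), with RPE65, the isomerase of the visual cycle, at 6.91 ± 0.26. The median of the list was −0.11, opposite in sign to its test.

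In lung, 380 genes lay above, first the surfactant proteins SFTPA2 and SFTPA1 at 8.81 ± 0.24 and 8.51 ± 0.25 and the capillary protein GPIHBP1 at 6.83 ± 0.24. Of 25 genes of lung epithelium and vessels 11 passed (adjusted p = 5.73e-15; the transcription factor NKX2-1 5.44 ± 0.21), and of 25 interferon response genes 18 (2.55e-18; IFIT5 4.85 ± 0.37). IFIT5 had an SD of 2.05 between the 4 lung arrays, which the pooled SE does not show, and the median level of the interferon list above the median of all groups was 2.53 at day 7, 1.01, 0.98 and 2.55 at days 14, 21 and 28 of the same run, and 2.42, 3.44 and 0.88 at days 1, 35 and 42 of the second run. At days 1, 7, 28 and 35, where that list was highest, lung arrays also held a signal in unnamed probe sets, given below. Whether the interferon genes go with lung or with that signal was not tested. Spleen held 375, with the chemokine CXCL13L2 at 7.07 ± 0.25, the lysozyme LYZ at 5.48 ± 0.30 and JCHAIN, which joins secreted antibodies, at 5.55 ± 0.27. There 10 of 22 T cell genes (7.6e-18; CD3E 4.77 ± 0.23), 9 of 22 B and plasma cell genes (1.86e-10), 10 of 14 of antigen presentation (7.88e-14), 14 of 27 of granulocytes and macrophages (7.6e-18) and 22 of 25 of the interferon response (3.18e-24) passed. Abdominal fat held 357, led by the chemokines CCL4 and IL8L2 at 7.27 ± 0.37 and 7.02 ± 0.25 and the mesenchymal transcription factor SNAI2 at 4.74 ± 0.23. Collagen and connective tissue genes passed in 17 of 33 cases (5.93e-12; COL1A2 3.43 ± 0.26) and cell cycle genes in 5 of 41 (5.93e-12). At day 21 the direction was reversed for CCL4 (−0.07), IL8L2 (−0.81) and the median of the cell cycle list (−0.41). Of 28 adipocyte genes 4 passed (adjusted p = 0.72) and ADIPOQ, the hormone adiponectin, was −1.04 ± 0.27, and 4.16 at day 21.

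**Figure D2:**
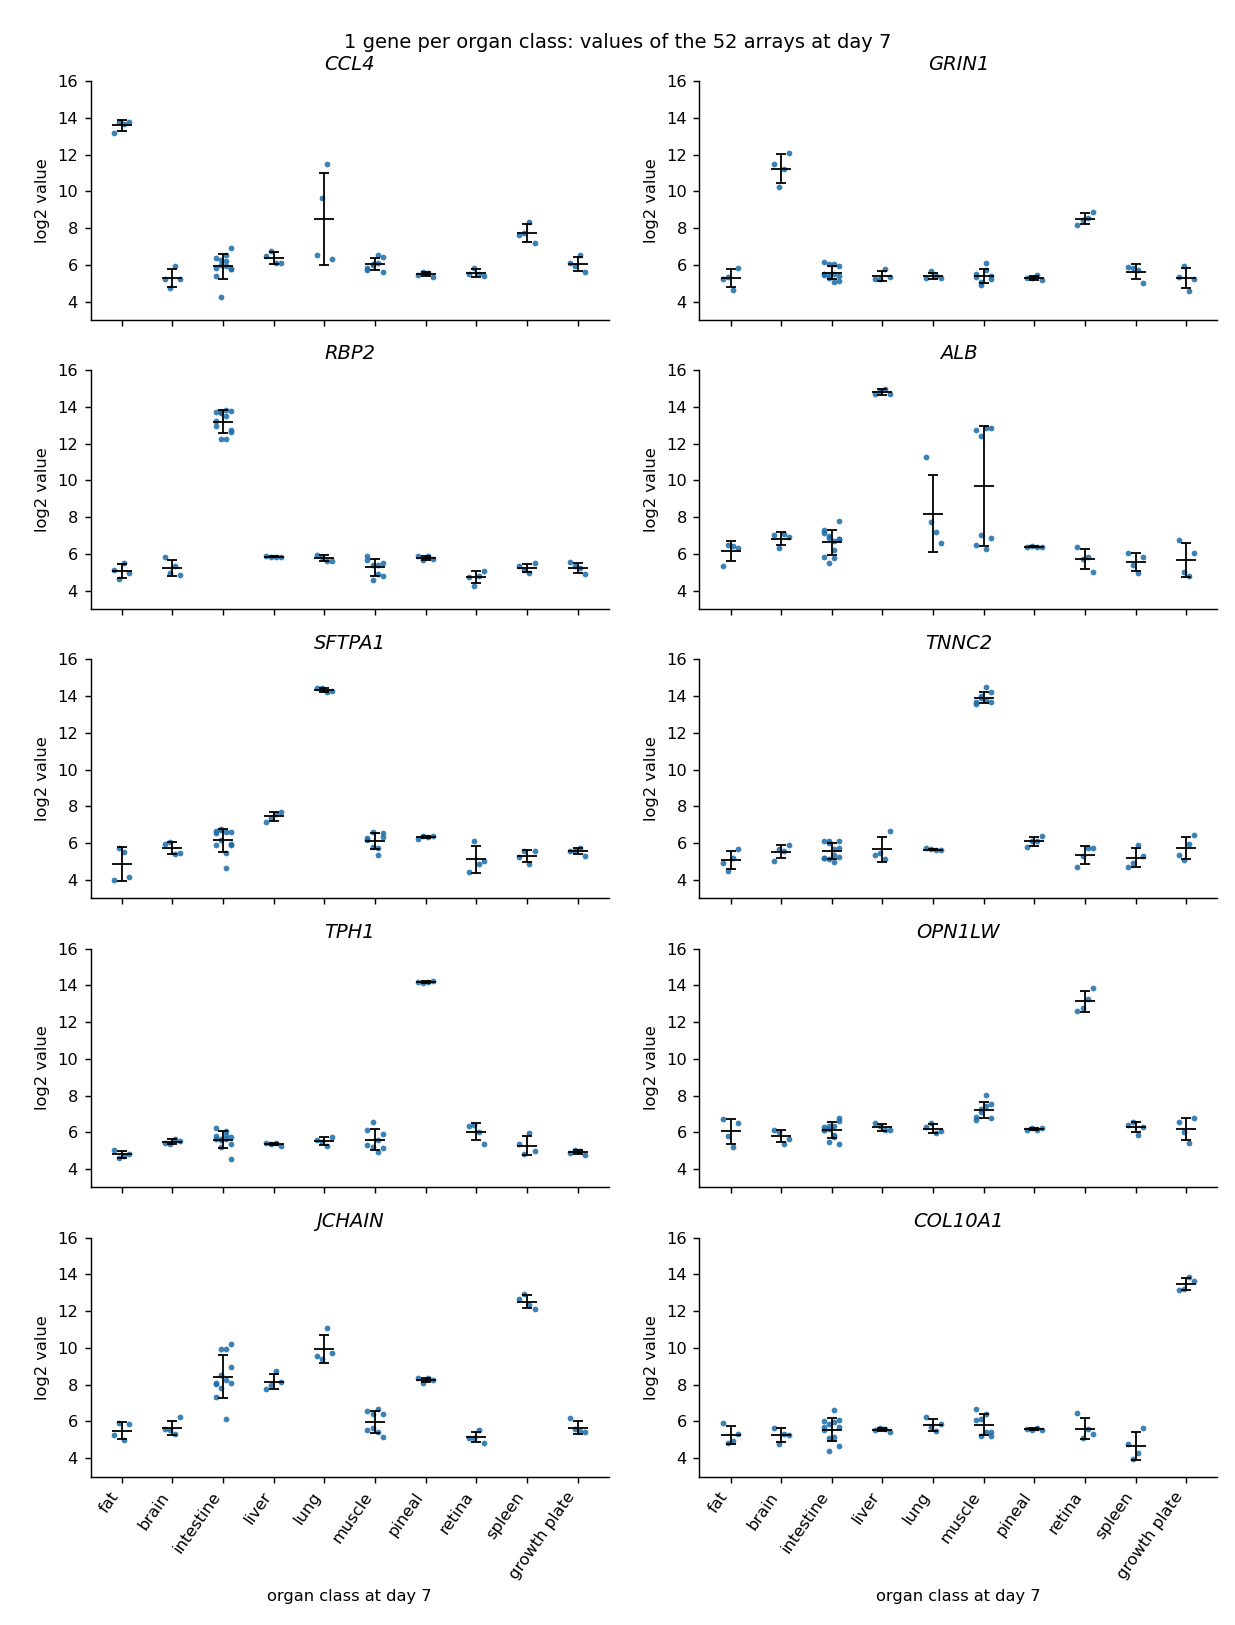
Deposited log2 values (y axis) of 1 gene per organ class on the 52 arrays at day 7 (x axis, 10 organ classes); points are arrays, bars the mean and SD. Each gene lies highest on the arrays of the class that it was drawn for, and ALB lies near 13 on the gastrocnemius arrays and near 7 on the pectoralis arrays, all shown as muscle.

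Every organ list that passed and is named here held with an estimated correlation, with adjusted p between 2.63e-18 and 0.0326. Counts fell to 138 in liver, 94 in intestine, 126 in muscle, 75 in growth plate, 55 in brain, 69 in retina, 49 in the pineal gland, 45 in lung, 47 in spleen and 35 in fat when a gene had to lie 4-fold above every other class. Brain moved to 343 at day 21, muscle to 185 and retina to 862, and brain to 302 with its second set of arrays. Muscle at day 21 counted gastrocnemius and the second set of pectoralis as separate arrays, though these match 1 to 1, as told below. With the mean of all probe sets of a gene, brain, fat, lung and pineal gland moved to 388, 234, 229 and 231.

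The first week was followed in 4 tissues. In liver, 765 genes were higher at day 7 than at day 0 and 836 lower, of 12810. Genes induced by interferon rose, with IFI6 at 5.87 ± 0.39 and IFIT5 at 4.28 ± 0.26 (log2 day 7 minus day 0 ± SE, 4 arrays each). So did AVD, the biotin-binding avidin (7.18 ± 0.43), and the lymphocyte granule proteins GZMA and GNLY (4.60 ± 0.24 and 4.44 ± 0.28). IGFBP2, a carrier of insulin-like growth factors, fell (−4.29 ± 0.19), and so did DIO2, which activates thyroid hormone (−3.59 ± 0.31), and the plasma protein HRG (−3.37 ± 0.36). Of 25 interferon response genes 18 rose and 0 fell (adjusted p = 7.22e-16), of 14 genes of antigen presentation 10 and 0 (5.92e-11; B2M 3.21 ± 0.23), of 22 T cell genes 7 and 0 (4.83e-09; CD3D 4.15 ± 0.20) and of 22 B and plasma cell genes 9 and 0 (1.95e-05). The median level of the interferon list, relative to all groups, was −0.19, −0.35, −0.03, 1.35, −0.14 and 1.12 at days 0, 1, 3, 7, 9 and 49. That of antigen presentation was −0.26, −0.28, −0.18, 0.98, 0.13 and 1.21 and that of T cell genes −0.21, −0.08, −0.1, 0.58, −0.05 and 0.72. Differences between these ages other than days 7 and 0 were not tested. Granulocyte and macrophage genes went both ways, 12 up and 5 down of 27 (adjusted p = 9.12e-06, and 0.0728 with an estimated correlation). Of 37 genes of oxidative phosphorylation 6 fell (9.12e-06; NDUFS4 −1.28 ± 0.18), and 6 of 23 of fatty acid oxidation fell (adjusted p = 0.00131, and 0.0992 with an estimated correlation; CPT1A, its entry step, −2.58 ± 0.33). These counts were the same adjusted over the list alone. Quantile normalization turned the balance of the calls to 776 higher and 530 lower, and centring each array on its median to 900 and 651.

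In pectoralis muscle, 262 genes were higher at day 7 and 406 lower, of 12790. The fast myosin heavy chain MYH1E rose most, by 6.90 ± 0.38, while another fast myosin, MYH1B, fell (−3.20 ± 0.37). Genes of sterol synthesis rose, with INSIG1, which controls it, at 3.83 ± 0.32 and the squalene epoxidase SQLE at 3.34 ± 0.36. Of 19 genes 7 rose and 0 fell (11 and 0 adjusted over the list alone; adjusted p = 3.29e-13). CSRP3, a protein of the muscle Z-disc, fell (−5.59 ± 0.37), as did PDK4, which restrains glucose oxidation (−4.41 ± 0.35), FKBP5, a target of glucocorticoids (−4.04 ± 0.40), and the slow myosin-binding protein MYBPC1 (−3.84 ± 0.39). Of 18 slow-fibre genes 1 rose and 8 fell (1 and 10 over the list alone; 1.78e-07) and of 14 fast-fibre genes 4 rose and 1 fell (5 and 1; 2.78e-06). Of 41 cell cycle genes 7 rose (17; 2.11e-12) and of 17 of glycolysis 4 rose (6; 6.17e-05). Of 33 of connective tissue 7 fell (11; 1.55e-09) and of 22 stress genes 7 fell (8; 1.31e-06; CYR61 −2.48 ± 0.39). Of 23 genes of fatty acid oxidation 6 fell (7; 0.000712, and adjusted p = 0.013 with an estimated correlation). Markers of other cell types fell too, but did not pass with an estimated correlation: of 27 adipocyte genes 1 rose and 3 fell (1 and 8; 0.0219, and 0.0538), of 25 cartilage genes 4 fell (4; 0.00534, and 0.192) and of 15 myelin genes 4 fell (5; 0.0288, and 0.0765). Nor did those of embryonic muscle, 4 of 21 lower (6; 0.0412, and 0.0815). The adjusted p was 0.0519 and 0.0599 for myelin without replicates 1 and 3, and 0.0724 and 0.0539 for embryonic muscle without replicates 1 and 2. For embryonic muscle it was also 0.0585 with the replicate number as a block and 0.102 with the mean of all probe sets. Quantile normalization left 224 calls in place of 668, and 354 were left without replicate 2 and 418 without replicate 3.

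In whole intestine, 196 genes were higher at day 7 and 111 lower, of 12056. GZMA (5.87 ± 0.24) and GNLY (4.39 ± 0.15) led, with PIGR, which carries antibodies across the epithelium (4.25 ± 0.27), the alpha globin HBA1 (4.05 ± 0.25) and BF2 and BLB1 of the major histocompatibility complex (3.32 ± 0.30 and 3.10 ± 0.10). APOA2, an apolipoprotein, fell (−3.31 ± 0.29), as did HPX, which binds free heme (−2.23 ± 0.22). Of 13 genes of antigen presentation 8 rose (adjusted p = 1.44e-14), of 19 T cell genes 6 (9.78e-13), of 25 of granulocytes and macrophages 8 (4.93e-14) and of 19 B and plasma cell genes 3 (0.000122), and 0 fell in each. Of 19 genes of sterol synthesis 8 rose (adjusted p = 7.74e-09, and 0.161 with an estimated correlation; MSMO1 2.86 ± 0.17), and of 41 cell cycle genes 6 fell (1.44e-14, and adjusted p = 0.125 with an estimated correlation; MCM2 −1.15 ± 0.12). All of these were the same over the list alone. The same ages of duodenum, taken in place of whole intestine, gave 1328 calls, of which 165 were shared.

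In brain, 62 genes were higher at day 7 and 53 lower, of 12650. Both ages spread widely, with a median SD of 0.4105 at day 7 and 0.4346 at day 0. The fit pooled them with brain at days 21, 28, 35 and 42 (0.0993 to 0.128), so the SE is too small for them. TF, the iron carrier transferrin (1.89 ± 0.31), the alpha globin HBA1 (1.54 ± 0.23), B2M (1.38 ± 0.21) and CD74 (1.38 ± 0.22) were higher, and PDK4 (−1.54 ± 0.35), KLF9, a target of thyroid and glucocorticoid hormones (−1.50 ± 0.23), and the midbrain transcription factor EN1 (−1.30 ± 0.25) lower. Of 14 genes of antigen presentation 3 rose, also over the list alone (adjusted p = 0.0383, 0.186 with an estimated correlation, 0.272 and 0.123 without replicates 1 and 4 and 0.168 with the mean of all probe sets), and MBP, at 0.31 ± 0.31, did not pass. The count was 0 with array weights or with the 2 ages alone and 44 with the mean of all probe sets, and it was 354, 50, 54 and 55 without replicates 1, 2, 3 and 4 in turn; other splits of the 8 arrays called up to 173 genes.

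**Figure D3:**
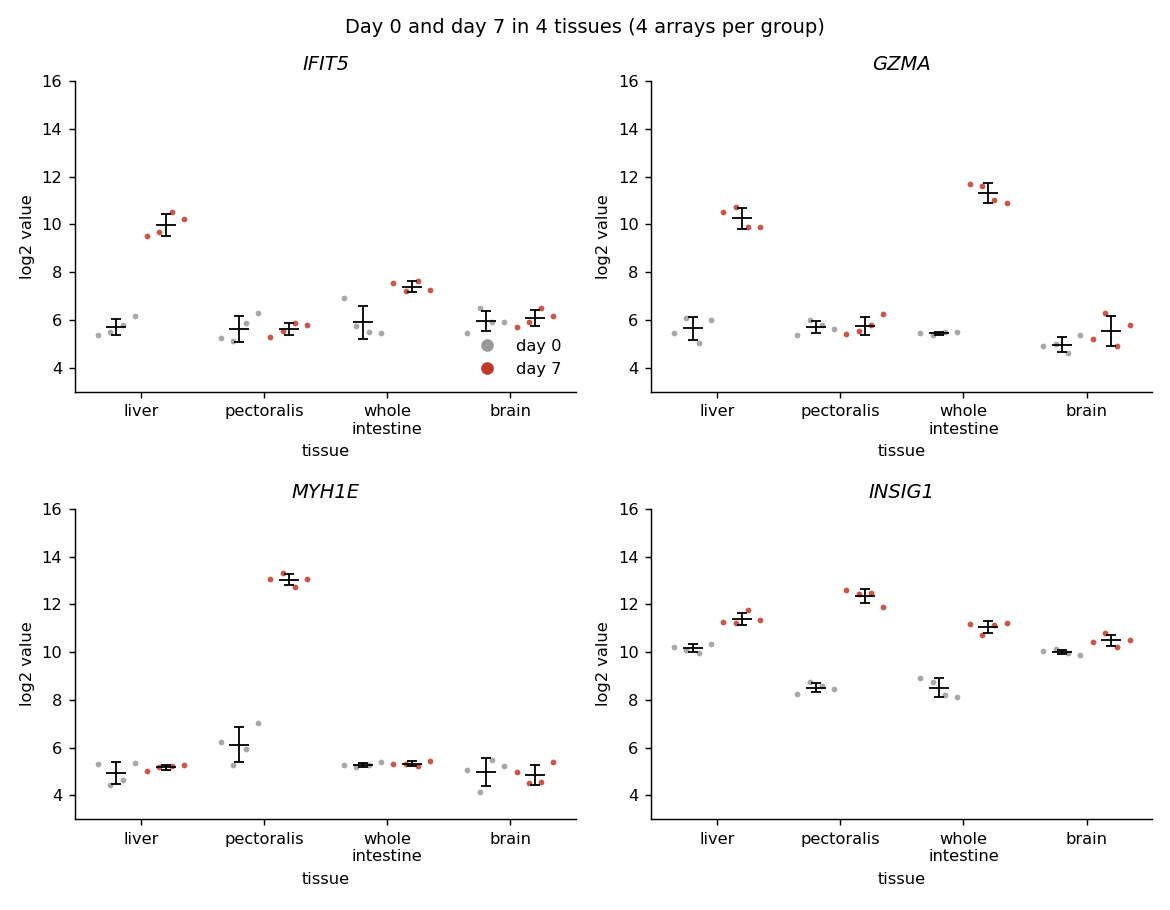
Deposited log2 values (y axis) of IFIT5, GZMA, MYH1E and INSIG1 at day 0 (grey) and day 7 (red) in liver, pectoralis, whole intestine and brain (x axis, 4 arrays per group); points are arrays, bars the mean and SD. IFIT5 differed by 4.28 in liver, GZMA by 4.60 in liver and 5.87 in whole intestine, and MYH1E by 6.90 in pectoralis.

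Abdominal fat was compared between days 49 and 10: 679 genes were higher at day 49 and 3104 lower, of 12622. Fat-storage genes rose: THRSP, a regulator of lipogenesis (7.05 ± 0.10), the lipid droplet protein PLIN1 (5.71 ± 0.15), the lipase LPL (5.37 ± 0.24) and ADIPOQ (5.32 ± 0.23). HBA1 (6.28 ± 0.18) and VWF, a protein of vessel walls (5.12 ± 0.31), rose too. The chemokines IL8L2 and CCL4 fell (−6.73 ± 0.31 and −6.71 ± 0.37), with PTGS2, an enzyme of prostaglandin synthesis (−5.13 ± 0.37), the cytokine IL6 (−5.02 ± 0.25) and the activin subunit INHBA (−5.52 ± 0.14). Of 28 adipocyte genes 16 rose and 0 fell (adjusted p = 4.6e-09) and of 24 of lung epithelium and vessels 6 rose and 1 fell (8.35e-05). Of 41 cell cycle genes 39 fell (adjusted p = 6.41e-14, and 0.226 with an estimated correlation; RRM2 −4.08 ± 0.29), as did 12 of 19 of sterol synthesis (0.00919, adjusted p = 0.397 with an estimated correlation and 0.0643 with quantile normalization; HMGCS1 −2.98 ± 0.28). Over the list alone these counts were the same. HINTW, a gene of the female-specific W chromosome, also fell (−6.12 ± 1.17), though both ages were labelled with males and females. It lay between 9.94 and 13.02 on the arrays of day 10 and between 5.8 and 5.94 on those of day 49. Age and a difference in sex between these groups thus cannot be told apart. Quantile normalization gave 1216 higher and 1923 lower. The median over all genes was −0.077 as deposited and −0.237 after centring each array.

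Retina was compared between days 35 and 9, with 2629 genes higher and 1336 lower of 12613. The lowest value of an array lay between 3.29 and 3.32 at day 35 and between 3.64 and 3.68 at day 9. Age and a batch within the run thus cannot be told apart. BSG, a glycoprotein needed by photoreceptors, rose (5.54 ± 0.10), and so did the thyroid hormone and retinol carrier TTR (5.01 ± 0.32) and the mitotic kinesin KIF20A (4.80 ± 0.09). UNC119, a photoreceptor trafficking protein, fell (−4.41 ± 0.20), with OPN1LW (−3.77 ± 0.19) and RD3, a regulator of retinal guanylate cyclase (−3.69 ± 0.10). Of 26 photoreceptor genes 2 rose and 12 fell, also over the list alone (adjusted p = 0.038, 0.445 with an estimated correlation, 0.1 with the mean of all probe sets and 0.101 with only the 2 ages), among them the cone opsin kinase GRK7 (−3.07 ± 0.12) and the arrestin SAG (−2.64 ± 0.14). The mean of all probe sets gave 2601 calls in place of 3965, and quantile normalization 2217 higher and 1724 lower.

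Spleen changed in 58 genes up and 55 down between days 1 and 14, of 12531. HINTW (6.73 ± 0.32) and HNRNPKL (3.34 ± 0.31), both of the W chromosome, led the higher genes, before NOS2, which makes nitric oxide (2.87 ± 0.43), CCL4 (2.86 ± 0.32) and the acute-phase protein SAA (2.21 ± 0.46). RHAG, an ammonium channel of red cells, rose (2.29 ± 0.36). HINTW lay between 12.2 and 12.74 on the arrays of day 14 and between 4.93 and 6.04 on those of day 1. Age and a difference in sex between these groups thus cannot be told apart. The condensin SMC2 (−1.97 ± 0.37) and the cell cycle kinase subunit CKS2 (−1.97 ± 0.35) fell, and so did SFTPA1 (−2.45 ± 0.40). Of 41 cell cycle genes 7 fell (18 adjusted over the list alone; adjusted p = 4.76e-23) and of 19 red cell genes 1 rose (3 over the list alone; 1.56e-06). Calls came to 24, 37, 53 and 58 without replicates 1, 2, 3 and 4 in turn.

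Lung at day 28 differed from day 7 in 0 of 12067 genes by limma (160 higher and 289 lower at an unadjusted p under 0.05). SFTPA1 differed by −0.05 ± 0.11, NKX2-1 by −0.26 ± 0.12 and the endothelial cadherin CDH5 by 0.24 ± 0.14; IFIT5, at 0.10 ± 1.00, had an SD between arrays of 1.96 at day 28 and 2.05 at day 7. The growth plate at day 21 differed from day 1 in 0 of 12276 genes by limma (1251 higher and 880 lower unadjusted). COL10A1 was −0.91 ± 0.31, COL2A1 −0.31 ± 0.26, MMP9, a protease of growth plate resorption, −3.10 ± 0.46 and MKI67, a marker of dividing cells, 2.04 ± 0.39, with adjusted p between 0.118 and 0.534. Of the 41 cell cycle genes 9 were higher adjusted over the list alone (adjusted p = 8.14e-09, and 0.578 with an estimated correlation). Without replicate 2 the growth plate gave 192 calls, and with labelled sex as a covariate 2.

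Regions of the small intestine were compared at day 28. Duodenum lay above jejunum in 1755 genes and below in 1138, of 12469. The lowest value of an array lay between 3.38 and 3.48 in duodenum and between 3.62 and 3.68 in jejunum. Region and a batch within the run thus cannot be told apart here. CDO1, which breaks down cysteine (5.81 ± 0.36), the glutathione transferase GSTA3 (5.58 ± 0.61), the antibody genes IGLL1 and JCHAIN (5.42 ± 0.32 and 5.20 ± 0.57) and MYH11, the myosin of smooth muscle (5.34 ± 0.34), were higher, and SLC6A6, a taurine transporter (−4.45 ± 0.26), and MUC2, the goblet cell mucin (−4.09 ± 0.35), lower. Of 33 connective tissue genes 20 were higher and 3 lower (adjusted p = 0.00606; LUM 4.29 ± 0.23), of 41 cell cycle genes 21 and 0 (0.00167; MKI67 2.85 ± 0.38). Of 37 of oxidative phosphorylation 15 and 1 were (0.000441), and of 28 of enterocytes and digestion 1 and 10 (0.0285, and 0.0858 without replicate 1), the same over the list alone. Each of the 4 lists had an adjusted p of 0.976 with an estimated correlation. Ileum differed from jejunum in 0 genes by limma (574 higher and 478 lower unadjusted), with the ileal bile acid transporter SLC10A2 at 3.19 ± 1.08 and the sucrase gene SI at 0.01 ± 0.20. Array weights gave 11 calls, and leaving out replicate 3 gave 83. Replicate 3 of ileum and replicate 3 of jejunum correlated at 0.9942, the highest of any arrays of different groups. Arrays within ileum reached at most 0.9874 and within jejunum 0.9868. The 0 calls thus do not show that the regions are alike.

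Cecal epithelia at day 14 lay above jejunum in 2885 genes and below in 1139, of 12672. The lowest value of an array lay between 3.35 and 3.38 in cecal epithelia and between 3.58 and 3.69 in jejunum. Region and a batch within the run thus cannot be told apart. RBP2 (−8.32 ± 0.12), the lipoprotein genes APOB and APOA4 (−7.36 ± 0.19 and −6.95 ± 0.28), SLC15A1 (−7.21 ± 0.45) and the disaccharidases MGAM and SI (−6.80 ± 0.34 and −6.49 ± 0.39) were lower. The water channel AQP8 (5.32 ± 0.20), the ribonucleotide reductase RRM2 (4.66 ± 0.14) and MKI67 (4.48 ± 0.23) were higher. Of 28 genes of enterocytes and digestion 2 were higher and 18 lower (adjusted p = 7.11e-09), of 24 of nutrient transport 2 and 19 (7.67e-08), each with an adjusted p of 0.178 with an estimated correlation. Of 41 cell cycle genes 38 were higher (1.9e-13, and adjusted p = 0.205 with an estimated correlation), and of 25 of the interferon response 1 was higher and 17 lower (9.69e-05, and adjusted p = 0.485 with an estimated correlation; MX1 −2.64 ± 0.68). Adjusted over the list alone these counts stayed the same. Quantile normalization gave 2117 higher and 1648 lower, and moved the median over all genes from 0.187 to 0.039.

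The 2 muscles were compared at day 7, where pectoralis lay above gastrocnemius in 556 genes and below in 596, of 12388. MYH1E (6.30 ± 0.36), the glycerol phosphate dehydrogenase GPD1 (4.67 ± 0.45) and INSIG1 (4.15 ± 0.31) were higher. The slow-fibre genes MYL3 (−6.57 ± 0.32), MYH7B (−6.05 ± 0.46), CSRP3 (−6.04 ± 0.30) and TPM3 (−5.39 ± 0.33) were lower, as were the calcium buffer PVALB (−6.45 ± 0.29) and PDK4 (−4.65 ± 0.32). Of 18 slow-fibre genes 1 was higher and 13 lower (3 and 13 adjusted over the list alone; adjusted p = 4.23e-18) and of 19 genes of sterol synthesis 14 were higher (14; 2.36e-13). Markers of other cell types moved along: of 32 genes of hepatocyte secretion 0 were higher and 17 lower (0 and 21; 1.72e-21), ALB by −6.07 ± 0.30 and FGG by −4.60 ± 0.29. Of 26 of granulocytes and macrophages 6 were lower (7; 2.1e-05) and of 14 of antigen presentation 5 (5; 0.00017). Calls numbered 667, 637 and 653 without replicates 1, 2 and 4.

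Gonads were compared on 3 or 4 arrays a group. Testes at week 17 lay above ovary in 1697 genes and below in 2138, of 12777. Sperm genes were higher, among them PLCZ1, which starts egg activation (7.34 ± 0.33), TPPP2 (7.60 ± 0.24) and AKAP14 of the sperm tail (6.86 ± 0.26). Lower were CYP19A1, the aromatase (−6.39 ± 0.31), the oocyte factor GDF9 (−6.10 ± 0.29), ZP2 of the egg coat (−5.44 ± 0.33) and the ovarian transcription factor FOXL2 (−5.32 ± 0.36). Of 36 testis genes 30 were higher and 1 lower (adjusted p = 2.76e-20), of 26 oocyte genes 2 and 14 (0.000124), and of 28 ovarian somatic genes 4 and 11 (0.0458, 0.052 without replicate 4, 0.0508 with labelled sex as a covariate, 0.0543 with quantile normalization, 0.069 with the stricter filter, and adjusted p = 0.341 with an estimated correlation); over the list alone these counts were the same. The 3 arrays of ovary at week 17 were labelled male.

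The arrays labelled oocytes at week 21, 2 of 4 also labelled male, lay above that ovary in 1418 genes and below in 1440. ZP3, an egg coat protein that granulosa cells make in birds (7.63 ± 0.39), and INHA, an inhibin subunit of granulosa cells (6.39 ± 0.31), were higher, while GDF9 (−5.66 ± 0.27), CYP19A1 (−5.71 ± 0.29) and the connective tissue genes DCN (−6.04 ± 0.26) and COL3A1 (−6.01 ± 0.28) were lower. Of 26 oocyte genes 2 were higher and 17 lower (adjusted p = 1.43e-07), and of 33 connective tissue genes 5 and 20 (4.01e-08, and adjusted p = 0.0803 with an estimated correlation), the same over the list alone. The values go against the label: relative to all groups, the median level of oocyte genes was 0.8 on these arrays and 2.79 in that ovary, and of ovarian somatic genes 2.11 and 1.02. Other splits of the 7 arrays called up to 1734 genes.

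Ovary at year 2 lay above week 17 in 688 genes and below in 665. Quantile normalization gave 853 higher and 616 lower, and centring each array on its median 834 and 548. The matrix protease MMP9 (4.58 ± 0.54), ZP3 (4.38 ± 0.42), the antibody gene JCHAIN (4.14 ± 0.39) and the steroid enzyme HSD17B1 (3.51 ± 0.51) were higher, and the beta-defensin AvBD10 (−4.45 ± 0.46) and TH, the first enzyme of catecholamine synthesis (−3.18 ± 0.29), lower. Of 33 connective tissue genes 13 were higher and 0 lower (adjusted p = 0.000189, and 0.501 with an estimated correlation; COL1A2 1.90 ± 0.34), also over the list alone. The count of 1353 went to 888 with the mean of all probe sets, 547 with labelled sex as a covariate, 522 without replicate 2 and 586 without replicate 3. Ovary was labelled male at week 17 and female at year 2, and in this fit only the oocyte group held both labels. The effect of labelled sex was thus estimated from the oocyte arrays alone.

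Brain at day 7 and pectoralis at day 21 each came in both runs of sample numbers, so that the same label could be compared. The second set of brain arrays lay above the first in 1429 genes and below in 2227, of 12532. Globins of the embryo were higher, HBZ by 5.45 ± 0.43 and HBE by 5.38 ± 0.35, as were HES5, a Notch target (4.24 ± 0.35), and HES6 of the same family (5.53 ± 0.42). TTR (−7.19 ± 0.38), MBP (−7.09 ± 0.37), the neuronal enolase ENO2 (−5.51 ± 0.41) and GFAP (−5.24 ± 0.34) were lower. Of 17 myelin genes 14 were lower (adjusted p = 5.44e-11), of 23 neuronal genes 2 were higher and 15 lower (1.73e-07) and of 41 cell cycle genes 26 and 1 (5.87e-14; CDC20 4.36 ± 0.37), the same over the list alone. Quantile normalization gave 1923 higher and 1807 lower and moved the median over all genes from −0.093 to 0.074.

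The second set of pectoralis arrays lay above the first in 3532 genes and below in 2489, of 12827. The first set stood apart: its arrays correlated with each other at 0.652 to 0.685 on average, and its mean profile at 0.507 with the second set and 0.915 with pectoralis of unclear age. Its median levels relative to all groups were 1.15 for contractile genes, −2.39 for oxidative phosphorylation and −1.78 for glycolysis, against 6.55, 0.74 and 1.48 at day 7. Muscle genes were higher in the second set, with MYH1B at 6.92 ± 0.36, the calcium store protein CASQ2 at 6.52 ± 0.42, the Z-disc protein MYOT at 6.36 ± 0.48 and the glycolytic enzymes PGAM1 (6.80 ± 0.38) and LDHA (6.42 ± 0.42), and the kinase SRC lower (−4.25 ± 0.36). Of 29 contractile genes 23 were higher and 0 lower (adjusted p = 1.2e-12), of 37 of oxidative phosphorylation 32 and 0 (2.19e-13; NDUFA10 6.67 ± 0.38), of 17 of glycolysis 12 and 1 (2.16e-05) and of 22 stress genes 15 and 0 (9.15e-06), the same over the list alone. Centring each array gave 4326 higher and 1145 lower and moved the median over all genes from −0.105 to 0.305.

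Labelled sex was compared within groups, between 192 arrays labelled male and 192 labelled female. In every group of 4 arrays, replicates 1 and 2 were labelled male and 3 and 4 female, so labelled sex went with replicate number. Only the 2 groups of 6 arrays broke this. By limma, 0 of 13005 genes differed (341 higher and 849 lower in males at an unadjusted p under 0.05). HINTW, which only females carry, was 0.13 ± 0.16 (adjusted p = 0.856), with a mean of 8.71 ± 3.07 (SD, n = 192) on arrays labelled male and 8.57 ± 3.02 (SD, n = 192) on those labelled female, and VLDLR, of the Z chromosome that males carry in 2 copies, was −0.05 ± 0.05. The median over 604 Z-linked genes was −0.0132 and over 12235 genes of other chromosomes −0.00964. On simulated data of this design, in which the labels were right by construction, 90% of genes shifted by 0.2 were recovered. Within the first run of sample numbers 7 genes were called, and without replicate 2 there were 97. In the latter, replicate 1 alone stood for males in the groups of 4 arrays.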

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

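The tests of signal near background, of a shift of Z-linked genes for another transcript (with its draws of the labels), and both tests of the matching muscle arrays were chosen only after the result was seen.

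Between day 0 and day 7 tissues changed differently, tested as an interaction over 12815 genes. The change differed between liver and pectoralis in 2348 genes, liver and brain in 1415, pectoralis and whole intestine in 1232, pectoralis and brain in 1061, liver and whole intestine in 781 and whole intestine and brain in 135. The interferon-induced IFIT5 rose by 4.29 more in liver than in pectoralis (adjusted p = 4.63e-10), by 2.79 more than in whole intestine (1.24e-05) and by 4.16 more than in brain (2.48e-09). GZMA of lymphocyte granules rose in whole intestine by 5.29 more than in brain (5.62e-12), and GNLY differed by 0.05 between liver and whole intestine (0.979). The myosin MYH1E rose by 6.84 more in pectoralis than in whole intestine (1.76e-15).

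A signal appeared in probe sets that no comparison used, on 10 of 28 lung arrays. Of 687 probe sets with neither a gene name nor a chicken or control prefix, 9 rose at least 4 above their median on some array. The mean of 6 of these was 7.05 and 6.94 in lung at day 1 (replicates 3 and 4), 7.73 and 11.05 in lung at day 7 (replicates 2 and 3), 9.28 and 11.29 in lung at day 28 (replicates 2 and 3) and 8.48, 10.52, 9.87 and 11.04 in lung at day 35 (replicates 1 to 4), against at most 6.07 on all 375 arrays of other tissues. The other 3 were highest in liver at day 56 (11.03, next group 7.8), in fat at day 21 (12.57, next 12.55) and in fat at day 49 (8.42, next 7.37).

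In 17 of 96 groups the mean of 1 array lay apart relative to the range of its group, which can be narrow; chance flags about 1 group in 20. Replicate 1 lay apart, with the range of the others after it, in brain at day 0 (6.612; 6.664 to 6.673), day 7 (6.611; 6.664 to 6.667), day 8 (6.609; 6.658 to 6.662) and day 9 (6.608; 6.659 to 6.663), duodenum at day 0 (6.522; 6.626 to 6.643), gastrocnemius at day 7 (6.559; 6.63 to 6.636), liver at day 49 (6.561; 6.64 to 6.643), oocytes (6.606; 6.637 to 6.643), and pectoralis at day 0 (6.595; 6.657 to 6.664), day 7 (6.585; 6.656 to 6.662) and day 21 (6.453; 6.588 to 6.595). In the other 6 the array lay close to its group in absolute terms: gastrocnemius at day 21 (replicate 3, 6.492; 6.482 to 6.483) and day 28 (replicate 1, 6.441; 6.434 to 6.435), lung at day 21 (replicate 1, 6.611; 6.605 to 6.605) and day 28 (replicate 3, 6.605; 6.608 to 6.608), the second set of pectoralis at day 21 (replicate 4, 6.442; 6.433 to 6.434) and retina at day 28 (replicate 1, 6.597; 6.608 to 6.61). In the wide groups of the first run, replicate 1 resembled an array of another group of its tissue at a median correlation of 0.97 (0.946 to 0.994), where replicates 2, 3 and 4 reached 0.882, 0.901 and 0.891. In brain at day 7, replicate 1 reached 0.994 with another group and a mean of 0.916 with its own. Replicates 2, 3 and 4 had means of 0.9045, 0.9046 and 0.9045 with that group, so replicate 1 lay nearest to its group by this measure. For a single gene, MBP in brain at day 28 was 11.77 in replicate 1 and between 10.16 and 10.23 in the others.

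The arrays of all 38 groups of the second run and 18 of the first, brain at days 0 and 7 and pectoralis at days 0 and 7 among them, spread widely at every level of signal. Differences between birds would move 2 probe sets of a gene together. Their deviations correlated at a median of 0.0238 in the second run, against 0.171 in the narrow groups, which argues against birds as the main source. It does not measure the share of birds, since added scatter lowers the correlation and dim probe sets were included. Signal near background is argued against by the ratio of the SD of the brightest probe sets to that of the dimmest, 0.905. Replicates 2 to 4 as the exact values of replicate 1 with independent scatter is argued against by their correlation given replicate 1, 0.325. Scatter on replicate 1 itself would also leave a correlation among the others. The test thus cannot decide on independent scatter on every array. Given another replicate in place of replicate 1, the correlation among the others was 0.47. The source of the spread stays open, and no biological explanation other than birds was tested.

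The level of HINTW, a W-linked gene, did not follow labelled sex: 83 of 192 arrays labelled female and 104 of 192 labelled male were on the side of the label. In 33 of 95 groups every array lay on the high side, in 42 every array on the low side, 20 were mixed and in 1 every array matched, so that most mismatches lay in whole groups of 1 level. For a probe set that reads another transcript, 3 other W-linked genes lay on the same side on a median share of 0.797 of arrays, which missed the bar of 0.8 set beforehand. Tests chosen afterwards argue against it: over the 30 matching arrays of the 11 groups that keep both labelled sexes, chosen by the W-linked level, Z-linked genes lay 0.175 higher in labelled males than other genes did, above all other of 100 draws of the labels (up to 0.131). Over all arrays this difference was −0.00356, and labels that differ from the sex of the birds would give both values, but why whole groups share 1 level stays open.

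Muscle arrays of 4 labels in the second run, gastrocnemius and pectoralis at days 21 and 28, matched 1 to 1: each array had its best match in 1 array of each other label, which made 4 closed sets with correlations from 0.966 to 0.980. Muscles that are alike at these ages are argued against, since the lowest matched correlation, 0.966, lay above the highest between arrays of the same label, 0.914. The 4 closed sets fit the explanation that the same 4 samples stand behind the 4 labels, and the second set of pectoralis at day 21, compared in the report, is among them. Muscle types at these ages were not compared.

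Other splits of the arrays called fewer genes than the real one for ages of liver (1601 real, 445 highest other), pectoralis (668, 0), whole intestine (307, 0), fat (3783, 0), retina (3965, 1) and spleen (113, 3). The same held for duodenum (2893, 0), cecal epithelia (4024, 51), the 2 muscles (1152, 0), oocytes (2858, 1734), brain sets (3656, 0) and pectoralis sets (6021, 0). Each was 1 of 35 splits, the smallest share that these arrays can give. At day 7 other draws called fewer for fat (357, 48), brain (595, 209), intestine (362, 46), liver (519, 150), lung (380, 52), muscle (336, 69), the pineal gland (375, 80), retina (461, 120) and spleen (375, 238), each 1 of 100 draws. For the growth plate (318, 375), 2 of 100 draws called as many, the real one included. Replicates may be technical, so these shares tell that the arrays divide by label, not that other birds would. Chance divisions of the arrays often gave as much for brain ages (115, 173, 11 of 35 splits) and the median of Z-linked genes (−0.0132, 0.0225, 14 of 100). Where the real split called 0 genes, every split calls as many, so the share was fixed and tells nothing about chance: lung ages (0, 343; 35 of 35), growth plate ages (0, 1; 35 of 35), ileum (0, 69; 35 of 35) and sex (0, 2; 100 of 100). With 3 arrays against 3 the 10 splits are too few to tell for testes (3835, 1) and ovary ages (1353, 0). For lung ages, a split that called 343 genes where the real one called 0 points to a structure of the samples other than age.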

How the results depend on the processing

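The day 21 alternatives without the first set of pectoralis arrays, those without liver at day 56, pectoralis at day 21 or genes of the W chromosome, and the organ classes with groups of the first run only were chosen after seeing the data. No filter on dim probe sets, the stricter filter, centring on the median and trend with robust fitting left all 29 counts on their side and within 1.5 times; the alternatives without those groups or genes and the first run only did so too.

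In brain, the 115 genes changed by day 7 became 0 with array weights, 0 with only the 2 groups compared and 44 with the mean of all probe sets, and 50 to 354 when a replicate number was left out. Pectoralis at day 7 against day 0 fell to 224 with quantile normalization and 354 to 449 without a replicate; spleen ages gave 24 to 58, the 2 muscles 637 to 855, ileum against jejunum 0 to 83 and 11 with array weights. Ovary ages gave 547 with labelled sex as a covariate, 888 with the mean of probe sets and 522 to 1348 without a replicate, retina ages 2601 with the mean of probe sets, and duodenum in place of whole intestine 1328. Growth plate ages gave 2 with labelled sex as a covariate, 0 to 192 without a replicate and 48 with the replicate number as a block. The numbers did not pair these arrays (correlations from −0.123 to 0.217, 1 of 4 best with its own number). The block left the other counts within 1.5 times. With it the embryonic muscle list in pectoralis did not pass (adjusted p = 0.0585), and 2 of the genes tested again came to pass.

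Of the genes that set organs apart, those 4-fold above every other class, fewer by construction, were 55 in brain, 35 in fat, 75 in growth plate, 94 in intestine, 138 in liver, 45 in lung, 126 in muscle, 49 in pineal gland, 69 in retina and 47 in spleen. At day 21 brain had 343, muscle 185 and retina 862, and without the first set of pectoralis arrays brain 329 and retina 848. The second set of brain arrays gave 302 in brain. The mean of all probe sets gave 388 in brain, 234 in fat, 229 in lung and 231 in the pineal gland.

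Some directions reversed. In fat, ADIPOQ turned to 4.16 at day 21 (3.99 without the first set of pectoralis arrays), CCL4 to −0.07 (−0.08), IL8L2 to −0.81 (−0.81) and the median of the cell cycle list to −0.41 (−0.4). In brain, GFAP turned to −0.5 at day 21 (−0.47) and −0.5 with the second set of brain arrays, MBP to −2.24 (−2.28) and −2.33, and the median of the myelin list to −0.25 (−0.24) and −0.34.

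For sex, 7 genes passed within the first run, 0 to 97 without a replicate number, and 79 over 30 arrays, those whose W-linked level matches the label in the 11 groups that then keep both labelled sexes. These were chosen by that level, so HINTW, at −6.74 there, was fixed by construction. The median of Z-linked genes went from −0.0132 to −0.0014 with quantile normalization, 0.0302 with the replicate number as a block and 0.165 over the 30 arrays. With that block, labelled sex was told from replicate number only through the 2 groups of 6 arrays. For all other changes here the cause was not tested. On simulated data a log2 difference of 1.2 was recovered in 40% of genes in the design of the growth plate and 94% in that of liver.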

Other observations

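The profile of abdominal fat differed between days 10 and 14. HINTW lay on the high side on 4 of 4 arrays at day 10 and 1 of 4 at day 14. The lowest value of an array lay between 3.6 and 3.64 at day 10 and between 3.36 and 3.4 at day 14. Age and a batch within the run thus cannot be told apart, and a difference in sex between these groups was not tested. ADIPOQ, the adipocyte hormone, was 6.16 ± 0.218 at day 10 and 11.63 ± 0.283 at day 14 (mean ± SD, n = 4 each), while the chemokine CCL4 went from 12.52 ± 0.183 to 6.82 ± 1.1. Over the adipocyte genes, the median level above the median of all groups was −0.09 at day 7 (second run) and, in the first run, 0.09 at day 10, 2.64 at day 14 and 3.12 at day 49.

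In brain labelled day 21, HBZ, a globin of the embryo, was 11.75 ± 0.596 and the myelin gene MBP 6.1 ± 0.18 (SD, n = 6), against 6.07 ± 0.0707 and 10.58 ± 0.792 at day 28 (n = 4). The profile of that group correlated at 0.916 with the second set of brain arrays at day 7.

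Duodenum held genes of the exocrine pancreas at a median of 4.48 above the median of all groups at day 0, 2.75 at day 7 and 0.05 at day 28. In gastrocnemius at day 7 the plasma protein gene ALB was 12.72 ± 0.202, and in pectoralis 6.65 ± 0.351 (SD, n = 4 each). The fast myosin MYH1E in pectoralis was 13.03 ± 0.243 at day 7 in the first run and 6.55 ± 1.37 at day 14 in the second. Each pectoralis group of the second run lay nearest a gastrocnemius group of that run (0.9718 to 0.9945). Age, run and the tissue of the arrays thus cannot be told apart.

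Liver labelled day 56 stood apart from other liver groups. ALB was 8.03 ± 0.297 there (n = 3), 15 ± 0.299 at day 49 and 14.81 ± 0.144 at day 7 (SD, n = 4 each). Its profile correlated at 0.265 with liver at day 49 and at 0.467 with pectoralis of unclear age, its nearest group. Of the 95 groups whose tissue has another group, 87 had their nearest group in the same tissue. Cecal epithelia lay nearest duodenum at day 35 (0.912), cerebral cortex nearest brain at day 42 (0.976), and ileum and jejunum at day 28 nearest each other (0.990).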
